A study of Drosophila melanogaster and Drosophila yakuba with 2 samples.

How the data were processed

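Single-cell RNA sequencing was analysed from 2 libraries, 1 from dsx-expressing cells of D. melanogaster males and 1 from D. yakuba males. Per the labels, about 100 flies aged 4 to 8 days went into each library, and the tissue was digested with Liberase DH for 45 min before nuclear tdTomato cells were sorted. The deposited values are counts, as raw UMI counts per gene and cell barcode made by the authors with Cell Ranger, with no normalization. The matrix headers name Cell Ranger 6.1.2 for D. melanogaster and 7.0.1 for D. yakuba, while the authors' processing notes name 7.1.0; how introns were handled and which genome builds were used are not given in the sources used here. The barcodes had already been filtered before deposit, with at least 521 UMIs per barcode in D. melanogaster and 502 in D. yakuba, so empty droplets and free RNA were not measured directly. The medians were 7136.5 and 7640 UMIs per barcode, and the libraries held 40.9 and 49.2 UMIs when counted in units of 1000000.

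The D. melanogaster list held 13968 features, of which 13920 are protein-coding in the BDGP6.54 annotation, 3 are noncoding RNA and 45 were not found there. roX1 and roX2, which are noncoding, were not in it and are not analysed here. The D. yakuba list held 16011 features, of which 15671 were numeric locus identifiers, 302 tRNA features and 37 a block that its makeup (13 protein, 22 tRNA and 2 rRNA features) marks as mitochondrial. The tables used here paired 0 of these locus identifiers with a D. melanogaster gene, and 1 symbol, Tsc1, stood in both lists. The comparison planned before the data were examined, which joined the libraries on 1:1 genes, needed such a table and was not run. The choices kept from that plan were the filters, the gene lists, the resolutions, the depth for thinning and the intervals. The comparisons within D. melanogaster, the minimum levels that define cell classes and the name-free comparison of the libraries were chosen after the data were seen.

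Cells with at least 300 genes and at most 15% mitochondrial UMIs were kept. In D. melanogaster 11 barcodes failed (1 for genes, 10 for mitochondrial UMIs), and in D. yakuba 167 (62 and 137, some for both). The mitochondrial share counted 13 protein genes in D. melanogaster and the whole block of 37 features in D. yakuba, rRNA features with it. The 15% limit is therefore not the same measure in both libraries, and the numbers that failed it cannot be compared. Scrublet, at an expected share of 6%, called 4 barcodes (0.0771%) in D. melanogaster and 2 (0.0340%) in D. yakuba; shares this far below the expected level mean that doublet calling did not work. The called barcodes were left out, but doublets remain in the data. The 5171 and 5710 kept cells were normalized to 10000 UMIs and log-transformed, and features seen in under 5 cells were dropped. The 3000 most variable genes were scaled (limit 10) and reduced to 40 principal components. A graph of 15 neighbours was divided by the Leiden method at resolution 1. In D. melanogaster 319 genes (members of the functional lists, with dsx and fru) were kept out of the variable genes, so that clusters were not drawn from the genes compared between them. TN1-like cells were clustered again with 20 components at resolution 0.5. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.

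Clusters were classed from levels of named genes over the summed UMIs of the cluster. A dsx cluster had at least 300 CPM of dsx, and a low-UMI cluster had a median below the library's median divided by 3. The abdominal class had at least 600 CPM of Ubx, abd-A and Abd-B together, the Antp class at least 300 CPM of Antp with less of these, and the class without Hox genes under 100 CPM in all. TN1-like clusters were Antp clusters with at least 50 CPM of unc-4 and 100 of TfAP-2. Transmitters were taken in the order Vmat (at least 5000 CPM), Gad1 (2000), VGlut (1000) and VAChT (400). These levels were set with the clusters in view, and they place outside the TN1-like class cluster 36 (49 cells, Antp at 1063 CPM with unc-4 at 2.79) and cluster 39 (38 cells, unc-4 at 121 CPM and TfAP-2 at 217 with abd-A at 756).

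For each comparison raw UMIs were summed over the cells of each class and scaled to CPM. A gene was compared with at least 30 UMIs over the sums and at least 50 CPM in either class, list members with at least 30 UMIs. A count of 0 was set to 3 over the group for a bound on the ratio. Intervals are exact: Poisson for levels, conditional binomial for ratios and binomial for shares of cells, each at 95%. They treat UMIs and cells as independent draws, which cells from pooled animals in 1 library are not, so they are too narrow for any statement about other flies. The rule for named genes, written before the data were examined for the planned comparison and applied here within D. melanogaster, gave the genes of the classes, the 10 highest and 10 lowest genes by ratio, and up to 4 members of each list with the largest ratios; members named beyond these were chosen after their values were seen. The 16 functional lists cover sex determination, dosage compensation, neuropeptides and their receptors, monoamine receptors, acetylcholine receptors, GABA and glutamate receptors, voltage-gated channels, innexins, dpr and DIP, beat and side, axon guidance, apoptosis, stress and dissociation, ribosomal protein and mitochondrial genes. A list's median log2 ratio was ranked among 10000 random lists of the same size matched on expression. The random lists were not matched on how far their genes vary together. For a list whose members shift as 1 block, an extreme percentile can therefore reflect a single small shift. Shares of cells with a UMI were taken with each cell thinned to 1000 UMIs, which left out 95 D. melanogaster cells.

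The libraries were compared without gene names in 10 draws of 4000 cells thinned to 2000 UMIs each, without mitochondrial features. The clustering settings were the same, except that no gene was held out of the variable genes, which for all kept D. melanogaster cells at full depth gives 47 clusters in place of 49. Of the kept cells, 4869 in D. melanogaster and 5384 in D. yakuba were deep enough. The procedure was tested on simulated data. The 95% intervals held the true ratio for 95.4% of 5621 genes. True log2 ratios of 1 and 2 were recovered within 0.5 for 98.0% and 97.0% of genes. Those counts came from the Poisson model that the intervals assume, so they check the computation and not the spread between cells. Of random lists of independent values, 11.7% fell in the outer 10% of percentiles, and lists whose members vary together were not simulated. Clustering of 2000 cells of 20 simulated types gave an adjusted Rand index of 0.996. These cells were drawn from mean profiles of clusters of the same library, without doublets and with no gene held out. The index therefore does not measure how well real types separate. Alternatives tried were stricter filtering at 500 genes, doublet calls kept, the 5% of cells with the highest doublet scores left out, other resolutions and another seed, classes from single cells at 1000 UMIs, thinning, a lower minimum of 10 UMIs, clusters weighted equally, the median over the clusters of each class (with 1 CPM added to both), and VAChT clusters alone.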

Results

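Neurons that express doublesex were sorted from the central nervous systems of adult males of Drosophila melanogaster and Drosophila yakuba and profiled by droplet single-cell RNA sequencing, with 1 library per species. The gene doublesex (dsx) encodes the transcription factor that carries the sex-specific output of the fly sex determination pathway, and dsx neurons run much of male courtship, including song. In both species dsx-GAL4 drove a nuclear tdTomato reporter, which served as the sort marker. The labels give about 100 flies per library, aged 4 to 8 days. The D. melanogaster library held 5186 barcodes and 40888960 UMIs, with a median of 7136.5 UMIs and 2323 genes per barcode. The D. yakuba library held 5879 barcodes and 49206210 UMIs, with a median of 7640 UMIs and 2320 genes. After filtering, 5171 D. melanogaster and 5710 D. yakuba cells remained. With 1 library per species there are no replicates, so no value below carries a test, and every interval is an exact 95% interval that covers counting error only.

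The design asks whether the makeup of the circuits that pattern courtship song differs between the species. The D. melanogaster features carried gene names, while 15671 of the 16011 D. yakuba features were numbers, of which 0 matched the reference tables used here. Named genes are therefore described within the D. melanogaster library, and the species are set side by side only by quantities that need no names.

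dsx, the gene behind the sort, was detected in most but not all clusters of the D. melanogaster library. It stood at 918 CPM (UMI counts scaled to a total of 1000000; 908 to 927) over all kept cells, and 44 of the 49 clusters, holding 4554 cells (88.1%, 87.2 to 88.9), carried it at 300 CPM or more and were not low in UMIs. At 1000 UMIs per cell, a dsx UMI was found in 58.0% (56.6 to 59.5) of the 4544 cells of these clusters that were deep enough, and in 96.6% of their 4554 cells unthinned. Clusters with little dsx held 442 cells (8.55%, 7.80 to 9.34), and among the 426 of these with enough UMIs the share was 6.57% (4.41 to 9.36), at median depths of 3173 against 7512.5 UMIs. A group of 40 of these cells held 214 of their 319 dsx UMIs, and without it the other 402 cells (7.77%) had dsx at 66.0 CPM (54.0 to 79.9). A further 175 cells (3.38%) lay in 2 low-UMI clusters, with a median of 1244 UMIs and dsx at 469 CPM (401 to 544) when summed. The 2 were unlike. The cluster of 123 cells, led by whe and lcs, had dsx at 625 (535 to 726). Its sums held Vmat (2853), Gad1 (1046), VGlut (315) and VAChT (293). The cluster of 52 cells had dsx at 10.7 (0.271 to 59.5) with VAChT at 1357, and is not counted among the 442 cells with little dsx. Most markers of other cell types were near 0 in the dsx clusters, with repo at 0.259 CPM and alrm at 1.81 for glia, Mhc at 0.569 for muscle, ninaE at 0.155 for photoreceptors, Hml at 0 for hemocytes and Lsp2 at 0 for fat body. Higher levels were found for Pxn (141) from the hemocyte list, FASN1 (113), Apoltp (15.6) and apolpp (6.91) from the fat body list, and nrv2 (63.4) from the glial list, while the neuronal gene nSyb stood at 2835. In the BDGP6.54 annotation dsx (FBgn0000504) lies on 3R from 7924323 to 7967408 on the minus strand. fruitless (fru, FBgn0004652, 3R from 18414273 to 18545586, minus strand), the other transcription factor gene of the pathway, stood at 797 CPM (789 to 806).

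The dsx cells of D. melanogaster split by Hox genes into a large class with little of any, a small class led by Antp and a class with abdominal Hox genes. Hox genes mark segments of the ventral nerve cord and are off in most of the brain. The class without Hox genes held 2614 cells in 18 clusters, 50.6% (49.2 to 51.9) of kept cells. The class with Antp and under 600 CPM of abdominal Hox genes held 350 cells in 3 clusters, 6.77%, of which a cluster of 49 cells had Ubx at 347 CPM. The class with 600 CPM or more of Ubx, abd-A and Abd-B together held 1590 cells in 23 clusters, 30.7% (29.5 to 32.0). Abd-B (FBgn0000015) stood at 1007 CPM in the abdominal class and 8.33 in the class without Hox genes, abd-A (FBgn0000014) at 456 and 3.83, and Ubx (FBgn0003944) at 216 and 2.48. The sort, dissociation and filters can all set these shares.

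Transmitter genes differed between the Hox classes. In the class without Hox genes, 2529 of 2614 cells lay in clusters with VAChT, which encodes the vesicular acetylcholine transporter, 53 in clusters with Gad1, the GABA synthesis enzyme, and 32 in a cluster with VGlut, the vesicular glutamate transporter. All 350 cells of the Antp class lay in VAChT clusters. The abdominal class was mixed, with 642 cells in VAChT clusters, 645 in Gad1 clusters, 190 in VGlut clusters, 85 in clusters with Vmat, the vesicular monoamine transporter, and 28 in a cluster below the minimum for each of these genes. Summed over each class, Gad1 stood at 1954 CPM in abdominal and 260 in Hox-negative cells, VGlut at 291 and 90.9, and VAChT at 526 and 855. The Vmat cells formed a cluster of 59 led by Trh and SerT, the serotonin synthesis enzyme and transporter, and a cluster of 26 led by DAT and ple, the dopamine transporter and tyrosine hydroxylase. Vmat itself stood at 21398 and 23965 CPM in the serotonin-gene and dopamine-gene clusters.

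**Figure D1:**
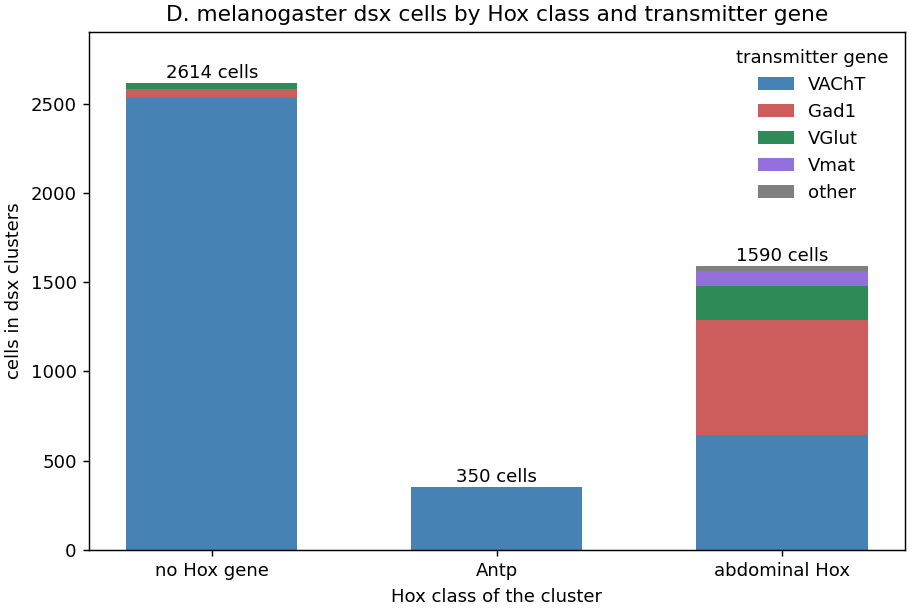
Cells of the 44 dsx clusters of the D. melanogaster library (y axis, number of cells) by Hox class (x axis), with bar segments for the transmitter gene of each cluster. Of 2614 cells without Hox genes, 2529 lay in VAChT clusters, against 642 of 1590 abdominal cells.

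Abdominal and Hox-negative dsx cells also differed in genes held out of the clustering. The neuropeptide genes that differed most rested on few clusters. Among 24 measured, AstA stood at 325 CPM in abdominal and 5.59 in Hox-negative cells, Crz at 94.8 and 1.81, Ms at 249 and 12.9, Proc at 750 and 50.1, and Dh31 at 473 and 41.4. Single clusters of 28 to 96 cells held 72.1% of the abdominal AstA UMIs, 99.3% of Crz, 98.1% of Ms, 89.5% of Proc and 75.5% of Dh31, and without its leading cluster each stood at 95.6, 0.741, 4.86, 83.0 and 119 CPM in that class. In the other direction, Mip stood at 0.188 and 35.0, NPF at 0.939 and 29.3, Ilp7 at 3.13 and 28.3, and Dh44 at 40.2 and 228, with 95.2% of the Hox-negative NPF UMIs in a cluster of 67 cells. Other members were spread, as with Gpb5, whose leading cluster held 11.4% of abdominal and 10.9% of Hox-negative UMIs, and Dh44, at 34.1% and 29.7%. The list's median log2 ratio was 0.10, at percentile 96.2 of 10000 random lists matched on expression, and -0.34 at percentile 0.02 when VAChT clusters alone were compared, and it was 0 when the median over clusters of each class was used, so the list as a whole had no stable direction. Cytoplasmic ribosomal protein genes were higher in abdominal cells, with a median log2 ratio of 0.46 over 29 genes, above every random list (RpS2, 2039 against 1368). The 13 measured mitochondrial genes had a median of 0.57, also above every random list. All 29 ribosomal protein genes and all 13 mitochondrial genes were higher, so each list moved as a block. Its percentile does not count independent genes. The list of stress and dissociation genes was lower in abdominal cells, with a median of -0.94 over 16 genes, below every random list. Of these genes 11 were lower and 5 higher, with 7 over 2-fold lower and 1 over 2-fold higher. Hsp23 stood at 242 against 965, Hsp26 at 414 against 1623, Hsp27 at 212 against 590 and Hr38, an activity-regulated nuclear receptor gene, at 818 against 1502.

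Monoamine receptor and axon guidance genes were lower in abdominal than in Hox-negative cells. Monoamine receptor genes had a median log2 ratio of -0.26 over 16 genes (percentile 0.15), with Dop1R1 at 116 against 325 CPM, 5-HT2A at 28.7 against 72.7, and Octbeta1R the other way at 121 against 58.9. Axon guidance genes had a median of -0.26 over 32 genes (percentile 0.01), with trn at 132 against 445 and Fas3 at 90.7 against 240, while robo2 stood at 95.5 against 22.8. The dpr and DIP genes, which encode pairs of cell surface proteins that bind each other, had a median of -0.28 over 31 genes, below every random list, but a median of 0.01 at percentile 65.0 among VAChT clusters alone. DIP-alpha (32.8 against 3.47) and DIP-lambda (116 against 21.1) were higher in abdominal cells within that list, and DIP-zeta (9.89 against 32.2) and DIP-eta (8.14 against 21.5) lower. Voltage-gated channel genes had a median of 0.10 over 23 genes (percentile 96.8), with the sodium channel gene para at 2347 against 1580. Neuropeptide receptors (-0.11, percentile 23.6), acetylcholine receptors (-0.14, percentile 9.78), GABA and glutamate receptors (-0.04, percentile 44.0), beat and side genes (-0.15, percentile 2.84), apoptosis genes (-0.25, percentile 1.74), sex determination genes (-0.09, percentile 27.7), dosage compensation genes (-0.13, percentile 24.5) and innexins (0.01, percentile 52.8) completed the lists. As part of the identity of the classes, pros, a transcription factor gene, stood at 771 CPM in abdominal and 24655 in Hox-negative cells, 32.0-fold lower (31.4 to 32.6). The 4 fixed markers of immature neurons had a median log2 ratio of -1.50 (percentile 0.09), with dati lower (88.2 against 866) as were Hey and nerfin-1, and Imp alone higher (1017 against 97.8). Hey and nerfin-1 set this median, though they had only 48 and 44 UMIs over all dsx clusters (1.24 and 1.14 CPM).

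dsx differed little between Hox-negative and abdominal cells, while fru was lower in abdominal cells. dsx stood at 937 CPM (923 to 950) in Hox-negative cells, 922 (907 to 937) in abdominal cells and 1231 (1194 to 1269) in Antp cells. fru stood at 991 (977 to 1005) in Hox-negative cells, 566 (554 to 577) in abdominal cells and 1171 (1135 to 1208) in Antp cells. Within the abdominal class, fru stood at 820 (799 to 842) in VAChT clusters, against 1004 in Hox-negative VAChT clusters, 347 (332 to 363) in Gad1 clusters and 284 (261 to 308) in VGlut clusters. Over the 44 dsx clusters fru ranged from 35.3 CPM, in a VGlut cluster of 46 abdominal cells, to 3190 in a VAChT cluster of 63 Hox-negative cells. In VAChT clusters alone, at 1000 UMIs per cell, a fru UMI was found in 41.8% of Hox-negative and 37.8% of abdominal cells. Over whole classes a fru UMI was found in 60.3% of Antp cells, 41.5% of Hox-negative cells and 26.7% of abdominal cells, and in 10.3% (7.61 to 13.6) of cells in clusters with little dsx. Unthinned, these shares were 93.7%, 66.3%, 63.3% and 24.4%, and thinning dropped 0, 9, 1 and 16 cells respectively.

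**Figure D2:**
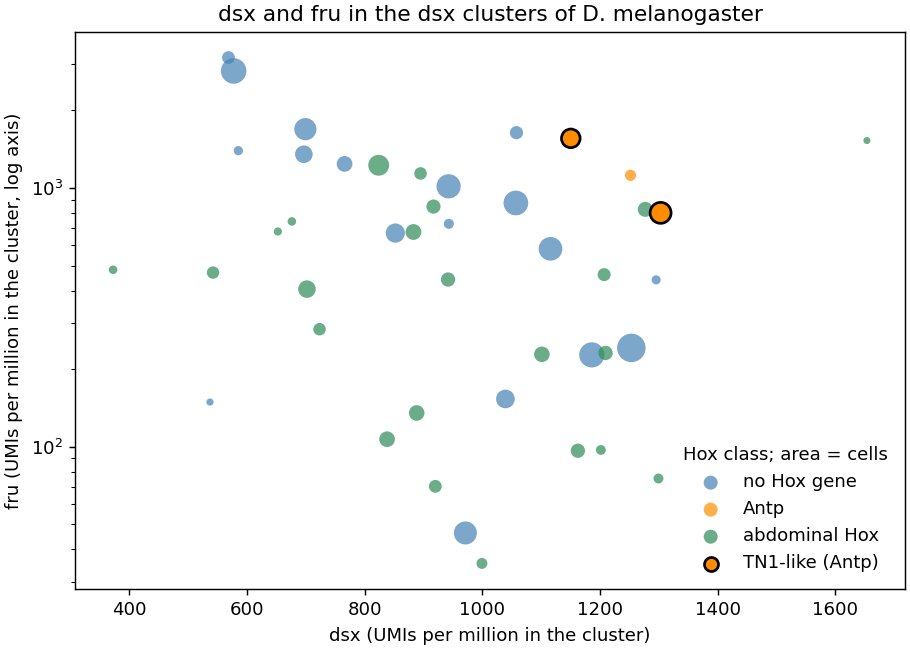
Each circle is 1 of the 44 dsx clusters of D. melanogaster, with dsx on the x axis and fru on a log y axis (CPM of the cluster), area by number of cells and colour by Hox class; black rims mark the TN1-like clusters. fru spans 35.3 to 3190 CPM, and the TN1-like clusters lie toward the right.

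TN1-like cells, the class closest to the thoracic song neurons, made up a small share of the D. melanogaster library. TN1 neurons are dsx neurons of the thoracic lineage 12A, which uses acetylcholine and expresses unc-4, TfAP-2 and grn. Clusters 10 and 14 carried Antp, with abdominal Hox genes below the minimum, together with unc-4 and TfAP-2, and held 168 and 133 cells. Their 301 cells made up 5.82% (5.20 to 6.49) of kept cells and 6.61% (5.91 to 7.37) of cells in dsx clusters. unc-4 (FBgn0024184, X from 17768569 to 17778708) stood at 136 CPM in these cells and 12.7 in the other dsx clusters, TfAP-2 (FBgn0261953, 3L from 21586828 to 21613349) at 307 and 24.8, grn (FBgn0001138) at 613 and 43.9, and Antp (FBgn0260642) at 1258 and 132. dsx stood at 1225 (1183 to 1268) and fru at 1185 (1144 to 1228), against 936 and 805 in the other dsx clusters. The minimums for these genes were set with the clusters in view. They left out another Antp cluster of 49 cells (0.948%), led by caup, kn and disco, and an abdominal cluster of 38 cells (0.735%), led by CG9650 and mid.

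By size alone, 22 of 3159 genes stood over 4-fold higher in TN1-like cells than in the other dsx clusters, and 77 over 4-fold lower. Between medians over the clusters of each side, the numbers were 54 and 28. A gene high in few of the other 42 dsx clusters does not raise their median. The TN1-like side had only 2 clusters, so its median is their mean, which a gene high in either raises. For such genes the measure leans toward TN1-like cells. The 10 highest were CG9512, bnl, bnb, mthl10, Mipp1, mid, CCHa2, CAH7, grn and H15. Apart from CCHa2 these genes were open to the clustering and describe what set the clusters apart. CG9512 and Mipp1 came almost wholly from cluster 10, so they are no trait of the TN1-like class as a whole. bnl, which encodes an FGF ligand, stood at 590 CPM against 21.2, a ratio of 27.8 (25.5 to 30.3). Cluster 10 alone had bnl at 1028 and mthl10 at 145, against 590 and 81.2 over both TN1-like clusters. Both ratios thus lean on cluster 10. mid and H15, T-box transcription factor genes, stood at 144 against 7.36 and at 61.5 against 4.44. The 10 lowest were Proc, CG12239, bi, Fer2, otp, Ms, AstA, AnxB9, Pka-C3 and Tk, of which Pka-C3 and Tk had 0 UMIs in TN1-like cells. A gene very high in a single cluster of the other side can set such a ratio of sums. CG12239 stood at 138922 CPM in a cluster of 28 cells and 26.7 in the rest of the kept cells. AnxB9 stood at 1837 in another cluster of 28 cells and 13.1 in the rest. Low ratios of this kind do not place TN1-like cells below most other dsx clusters.

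Neuropeptide genes were lower in TN1-like cells than in the other dsx cells summed, where few clusters held most of the UMIs of several of them, and not lower as a list than in the median cluster. Over 24 genes the median log2 ratio was -1.75, below every random list, for the sums, and 0 (percentile 24.9) against the median over clusters. In the latter measure 8 genes were lower, 11 higher and 5 equal. Several genes, such as Crz and Mip, had a median of 0 over the other dsx clusters, so TN1-like cells could not be lower for them. Proc stood at 1.90 CPM against 360, AstA at 1.52 against 147, Ms at 1.14 against 117 and sNPF at 15.9 against 280. The medians over the other 42 dsx clusters were 16.1 for Proc, 4.42 for AstA, 1.78 for Ms and 19.0 for sNPF, and single clusters held 82.8%, 70.6%, 92.4% and 41.5% of their UMIs. Tk had 0 UMIs in TN1-like cells against 65.9 CPM in the other dsx clusters, a log2 ratio of at most -5.86 when 0 is set to 3 UMIs over the group. The median of Tk over those 42 clusters was 3.14 CPM, and a cluster of 49 cells held 35.8% of its UMIs. CCHa2 stood at 802 against 46.6, a ratio of 17.2 (16.1 to 18.4), and came from a part of these cells only. Neuropeptide receptors went both ways, with a median of 0.06 over 27 genes (percentile 90.2) for the sums. It was 0.41, above every random list, against the median over clusters, where the TN1-like side is the mean of 2 clusters. Receptors for NPF and trissin were higher (NPFR, 114 against 25.4; TrissinR, 290 against 79.9), as was the FMRFamide receptor gene FMRFaR (161 against 57.0). AstC-R1 (5.69 against 44.9), CNMaR (23.5 against 130) and TkR99D (0.379 against 7.86) were lower.

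The beat and side genes and the acetylcholine receptor genes were lower in TN1-like cells than random lists under both measures. The beat and side genes, which encode partners in axon and synapse recognition, had a median log2 ratio of -0.63 over 21 genes, below every random list (-0.22, percentile 0.13, against the median over clusters), with side-VIII at 16.7 against 101, beat-VI at 82.0 against 292 and beat-VII at 133 against 418. The dpr and DIP genes had a median of -0.30 over 31 genes (percentile 0.01) for the sums and 0.10 (percentile 83.1) against the median over clusters, so they had no stable direction. DIP-lambda (3.04 against 62.7) and dpr10 (34.5 against 121) lay at the low end, and DIP-zeta (142 against 21.7), DIP-kappa (595 against 192) and dpr13 (1199 against 495) at the high end. Acetylcholine receptor genes had a median of -0.33 over 11 genes (percentile 0.49; -0.19, percentile 1.85, against the median over clusters), with mAChR-B at 1.52 against 18.3 and nAChRalpha1 at 179 against 354. Monoamine receptor genes had a median of -0.23 over 16 genes (percentile 1.12) for the sums and 0.0087 (percentile 40.5) against the median over clusters, with 5-HT1A at 31.1 against 174 and 5-HT7 at 26.9 against 95.5. Axon guidance genes had a median of -0.16 over 32 genes (percentile 1.43) for the sums and -0.054 (percentile 9.11) against the median over clusters, with Fas3 at 13.7 against 170.

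Mitochondrial genes were higher in TN1-like cells by a small and even amount, with a median log2 ratio of 0.37 over 13 genes (percentile 99.5). All 13 were higher, and the percentile does not allow for genes that vary together. Voltage-gated channels had a median of -0.07 over 23 genes (percentile 14.0). Among them the T-type calcium channel gene Ca-alpha1T was lower (227 against 604) and the hyperpolarization-activated channel gene Ih higher (1918 against 1268). The GABA and glutamate receptor list had a median of -0.06 over 14 genes (percentile 37.2), with the AMPA-type receptor genes GluRIA (43.3 against 189) and GluRIB (101 against 357) lower. Ribosomal protein genes (0.04, percentile 48.8), sex determination genes (-0.09, percentile 26.5), dosage compensation genes (-0.03, percentile 51.9) and innexins (-0.22, percentile 41.0) lay within the bulk of random lists. Apoptosis genes had a median of -0.33 (percentile 3.41) and stress and dissociation genes -0.24 (percentile 2.69; 0.053, percentile 51.0, against the median over clusters). The median over all genes compared was -0.04.

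**Figure D3:**
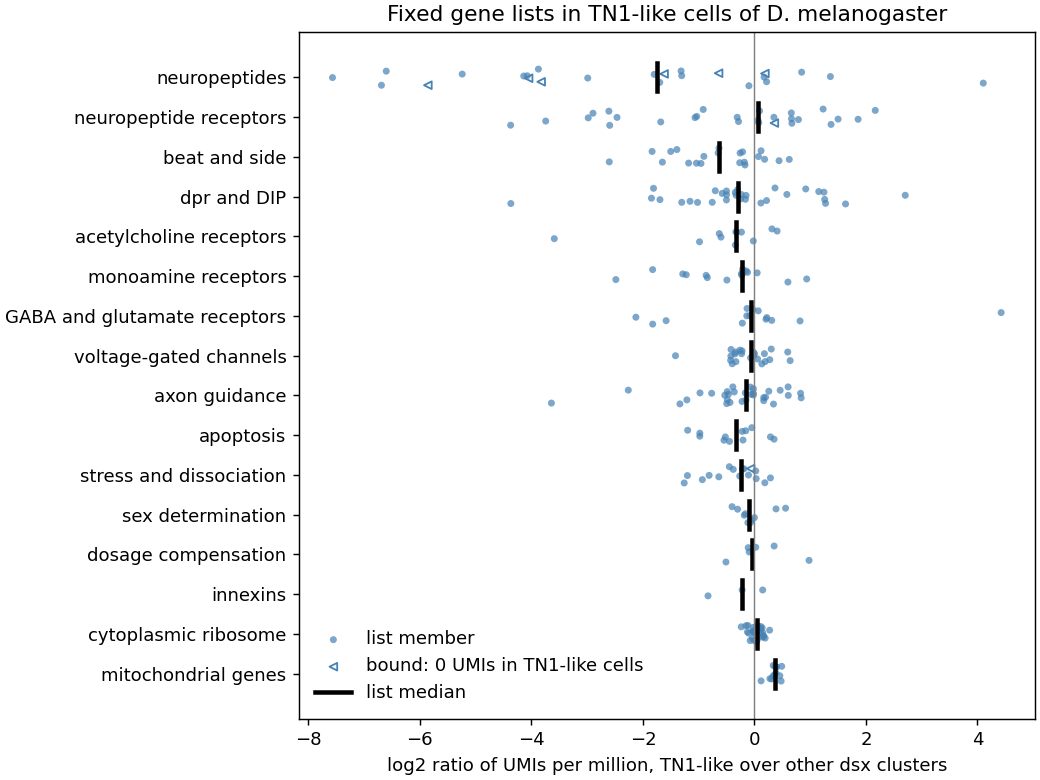
Log2 ratio of CPM, TN1-like cells over the other dsx clusters of D. melanogaster (x axis), for each member of the 16 fixed functional lists (y axis); black bars are list medians and open triangles are bounds for genes with 0 UMIs in TN1-like cells. For these sums the neuropeptide median lies at -1.75 (0 against the median over clusters), the beat and side median at -0.63 and the mitochondrial median at 0.37.

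TN1-like cells were not of 1 kind. Clustered again without the members of the functional lists, dsx or fru, they formed 5 subclusters of 93, 75, 58, 39 and 36 cells, and genes kept out of the clustering set them apart. Subclusters 1 and 2 lay wholly in cluster 10 and subclusters 3 to 5 in cluster 14, so contrasts with the other TN1-like cells partly restate these clusters. The median was 4916 UMIs in subcluster 1 and 9071 to 10956 in the others. dsx stood at 1106, 1452, 1586, 1137 and 468 CPM in subclusters 1 to 5, and fru at 493, 1033, 1678, 1341 and 1596, so that subcluster 5 had the least dsx (468, 400 to 544) and subcluster 1 the least fru (493, 436 to 555). The genes named from here on were chosen from those with the largest ratios, after their values were seen. Subcluster 1 was highest for the sex peptide receptor gene SPR (318 CPM against 44.2 in the other TN1-like cells), beat-VII (388 against 65.3) and dpr20 (549 against 122). CCHa2 was found in subcluster 2 alone, at 2876 CPM and in 57.3% of its cells, with 0 UMIs in the other 226 cells. Subcluster 2 was also highest for DIP-beta (498 against 8.95), DIP-eta (121 against 3.68) and the SIFamide receptor gene SIFaR (96.6 against 5.79). Subcluster 3 was highest for DIP-theta (402 against 6.32) and Ca-alpha1T (580 against 127). Subcluster 4 was highest for the leucokinin receptor gene Lkr (125 against 11.7) and the dopamine receptor gene Dop1R1 (294 against 57.5).

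Subcluster 5 was highest for dpr17 (831 CPM against 56.7 in the other TN1-like cells) and for the cholecystokinin-like receptor genes CCKLR-17D1 (122 against 6.59) and CCKLR-17D3 (271 against 20.7). It also had the most rpr (77.6 against 14.5), grim (72.0 against 15.8) and skl (133 against 17.1), which encode activators of programmed cell death. Summed, these stood at 283 CPM (230 to 343) in its 36 cells and 47.5 (39.0 to 57.3) in the other 265, a ratio of 5.95 (4.50 to 7.87). Of its cells 75.0% had a UMI of at least 1 of them, against 24.2% of the others, at median depths of 10314 and 8818 UMIs. Of other members of the pathway, the inhibitor gene Diap1 stood at 258 against 233, a ratio of 1.11 (0.879 to 1.38), while hid and Dronc had 1 UMI each in the subcluster, too few to place. Across the 44 dsx clusters the sum ranged from 28.0 to 489 with a median of 131, and 6 clusters lay above subcluster 5. In whole lists, 36 of 240 measured genes were over 4-fold higher in some subcluster than in the rest of the TN1-like cells. They included 5 of 6 neuropeptide genes, 10 of 17 neuropeptide receptor genes, 3 of 7 apoptosis genes and 8 of 29 dpr and DIP genes. Near or below the whole were beat and side (3 of 21), axon guidance (3 of 31), monoamine receptors (2 of 16), GABA and glutamate receptors (1 of 12) and voltage-gated channels (1 of 23). There were 0 among 10 acetylcholine receptor, 9 sex determination, 5 dosage compensation, 12 stress and dissociation, 29 ribosomal protein and 12 mitochondrial genes. Measured genes had at least 30 UMIs over all TN1-like cells, which a sparse gene can reach through the subcluster where it is high, as CCHa2 did. Of 32 neuropeptide genes only 6 were measured. The minimum can thus raise the shares of sparse lists, which cannot be ranked against those of abundant ones.

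**Figure D4:**
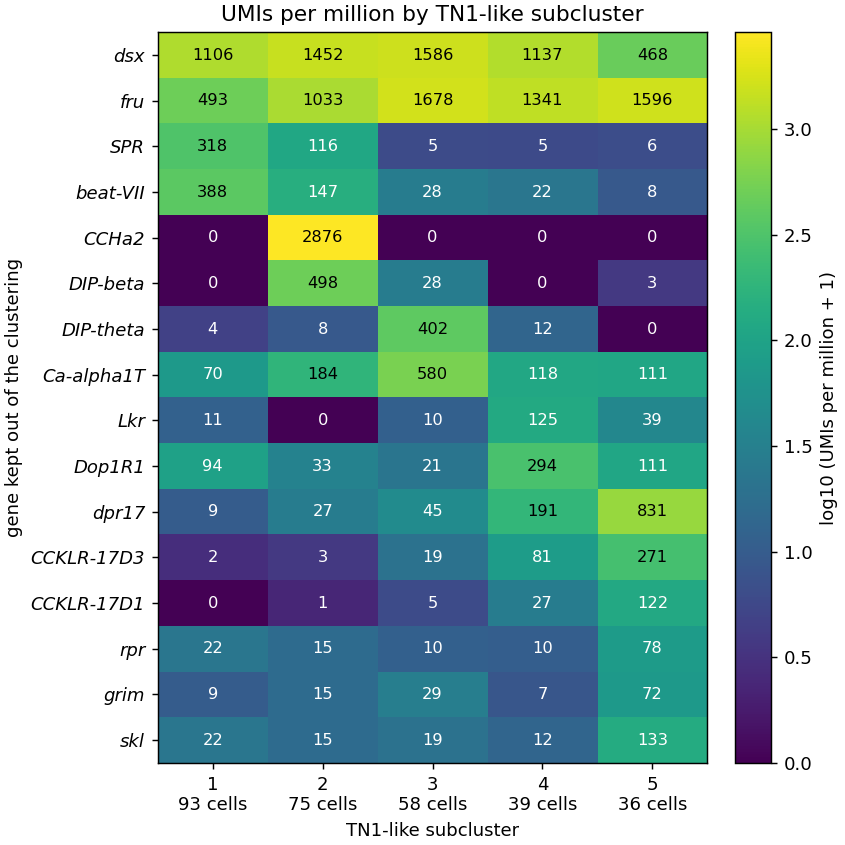
CPM of 16 genes kept out of the clustering (y axis) in the 5 TN1-like subclusters of D. melanogaster (x axis, with numbers of cells); colour is log10 of the value plus 1. CCHa2 is at 2876 in subcluster 2 and 0 elsewhere, and rpr, grim and skl are at 77.6, 72.0 and 133 in subcluster 5, where dsx is lowest at 468.

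With cells, depth and clustering settings matched, the libraries of the species gave similar numbers of clusters. In 10 draws of 4000 cells thinned to 2000 UMIs each, without mitochondrial features, the D. melanogaster cells gave a mean of 36.4 clusters (34 to 40 over draws) and the D. yakuba cells 35.7 (31 to 38). The effective number of clusters, which weights them by size, was 27.7 (26.0 to 30.3) and 27.6 (24.3 to 30.2). The largest cluster held 9.07% of cells in D. melanogaster and 10.0% in D. yakuba, and the median number of genes per cell was 1088 and 1050. Without thinning, with 5171 and 5710 cells, and with no gene held out of the variable genes, there were 47 and 46 clusters at resolution 1, the largest holding 8.59% and 5.92%, so the order of the largest clusters was not stable, and 38 and 34 clusters at resolution 0.5. The range over draws measures the subsampling, not the spread between animals. The settings largely fix such numbers: at resolutions 0.5, 1 and 2, D. melanogaster gave 38, 47 and 64 clusters and D. yakuba 34, 46 and 65. Similar numbers at the same settings therefore do not show that the species hold similar numbers of types. These numbers say nothing of which types the clusters are, so a type present in 1 species alone would not be visible in them.

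Few quantities could be set side by side between species by name. Tsc1, the only symbol in both feature lists, which encodes a growth regulator of the TOR pathway, stood at 20.1 CPM (18.8 to 21.5) in D. melanogaster and 21.7 (20.4 to 23.0) in D. yakuba, a ratio of 1.08 (0.982 to 1.18) that is within counting error of equality. The 13 protein genes of the mitochondrial genome took 1.61% of UMIs in D. melanogaster and 1.16% in D. yakuba, a ratio of 0.720 (0.718 to 0.723). The D. yakuba features counted here are the 13 protein features of a block of 37 that has the makeup of a mitochondrial genome, with 22 tRNA and 2 rRNA features besides. Over all barcodes the whole block took 2.62% of D. yakuba UMIs, above the 1.62% of the mitochondrial features in D. melanogaster. The D. melanogaster share counts 13 protein genes alone, while the rRNA feature KEF32_r02 by itself took 1.36% of D. yakuba UMIs. The shares of 2.62% and 1.62% are thus not the same measure, and only the ratio of 0.720 sets like features side by side. The totals behind these levels differ in what they count, since the D. melanogaster list was nearly all protein-coding and the D. yakuba list was not, and the matrices came from different Cell Ranger versions.

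**Figure D5:**
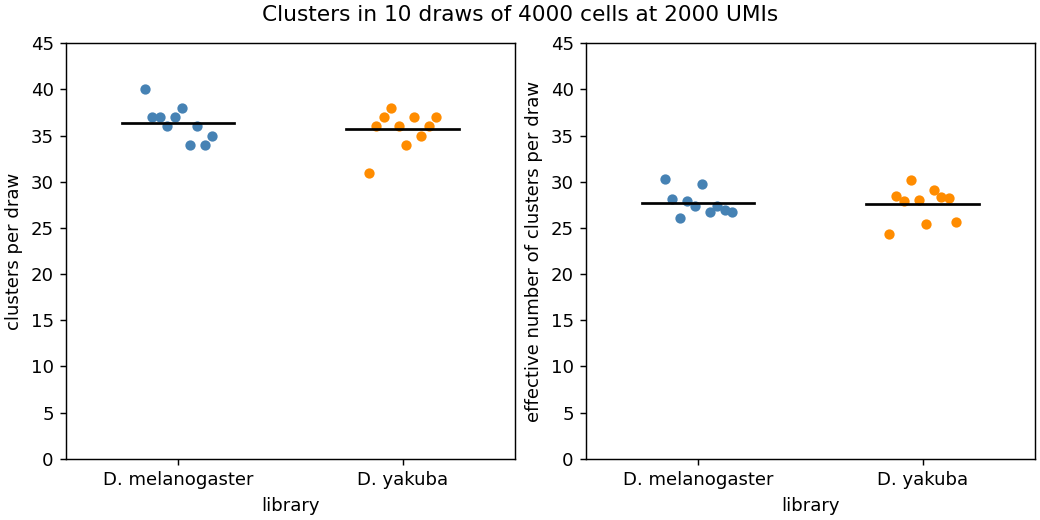
Number of clusters (left, y axis) and effective number of clusters (right, y axis) in each of 10 draws of 4000 cells at 2000 UMIs per cell from each library (x axis); points are draws and lines are means. The means are 36.4 and 35.7 clusters, and the draws of the species overlap.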

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

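All tests of the clusters with little dsx in this part were chosen after the result was seen, as was the median over clusters for the D. yakuba feature, while the other tests of that feature were chosen before it. None of these results was part of a planned comparison, and each is a signal in data that the main measurement leaves aside.

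In a sort for dsx cells, 8.55% of the kept D. melanogaster cells lay in clusters with little dsx (7.77% without a group of 40 cells that had dsx at 1134 CPM). A low-UMI cluster of 52 cells with dsx at 10.7 CPM is not part of this share. Too few UMIs are argued against for the 373 cells of 4 subclusters drawn without dsx, since summed over their cells the upper bound of dsx was at most 123 CPM, against 956 in dsx clusters. Doublets are argued against as the source of low dsx, since these cells had a median of 3173 UMIs and the library 7143. Summed over their cells, subclusters of 112 and 50 cells held VAChT (531 and 656 CPM), Gad1 (1342 and 2316) and VGlut (481 and 697), so mixed cells among them are not excluded. Whether single cells held several of these genes was not counted. Neurons of other types carried through the sort may be a source, since dsx stood at 14.3 CPM in 118 cells with VAChT at 1036. It stood at 1.36% of its level in dsx clusters in a subcluster of 93 cells whose sums held both Gad1 (2207 CPM) and VGlut (1045). That the reporter was on in cells with little dsx RNA cannot be told apart from neurons of other types, since 0 features were named for the sort marker, and no biological explanation was tested.

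A single D. yakuba feature, LOC6534338, held 6.21% of all UMIs, where the highest D. melanogaster feature, pros, held 1.31%. A single cell type as its source is argued against, since it took a median of 5.91% of UMIs over clusters of 50 or more cells. The value set beforehand as a sign of a single cell type, a lowest cluster under 1%, was met at 0.566% in 93 cells, but it does not separate 1 type that holds the feature from 1 that lacks it, and 36 of 37 such clusters lay over 3%. Free RNA is argued against, since the share in barcodes under 1000 UMIs was 0.571 times that in barcodes above the median (3.56% against 6.23%). Whether the D. melanogaster list leaves out a counterpart cannot be told apart from a species difference, since that list held 3 noncoding RNA features, and no biological explanation was tested.

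Another D. yakuba feature, KEF32_r02, held 1.36% of all UMIs, with no counterpart by name in the D. melanogaster list. It is annotated by its name as an rRNA feature of the mitochondrial block. Its share was 5.08% in barcodes under 1000 UMIs and 1.42% in those above the median, a ratio of 3.59. Differences between the species in these features were not tested.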

How the results depend on the processing

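For shares, levels and TN1-like cells, the alternatives of stricter filtering, doublet calls kept, other resolutions, single-cell classes, thinning and the minimum of 10 UMIs were planned; for lists between abdominal and Hox-negative cells and numbers of clusters, and for the other alternatives, they were chosen after the data were seen. Of 213 values under alternatives, over 44 results, 187 stayed within bounds: the 95% interval for shares and levels, 1.5 times for counts, and the same side of the outer 2.5% of random lists for list medians. Of 144 list medians, 15 changed sign or reached 0, of which 10 were within these bounds, such as stress and dissociation genes in TN1-like cells (0.053 against the median over clusters). Planned and not run, for want of a table of 1:1 genes, were the integration of the libraries by CCA or RPCA, merging without integration, all 1:1 genes as variable genes, scaling by size factors, assignment by a classifier and every ratio between species. No paired analysis was possible because each species has 1 library and the replicate numbers follow only the order of accessions. The share of TN1-like cells ranged from 5.82% to 5.97% under the filters, resolutions, doublet settings and seed, and 22 to 23 genes lay over 4-fold higher and 68 to 85 over 4-fold lower under the gene-level alternatives, except for 54 and 28 against the median over clusters.

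Among shares, the Antp class stood at 5.97% with at least 500 genes per cell, where it held 305 cells, as many as the TN1-like class, so no other Antp cluster met its definition. The class without Hox genes stood at 52.1% with the 5% highest doublet scores left out; the cause was not tested. As shares of cells in dsx clusters, TN1-like cells stood at 6.61%, the class without Hox genes at 57.4%, the Antp class at 7.69% and the abdominal class at 34.9%, which the smaller denominator alone produces. Depth limits the single-cell classes: at 1000 UMIs per cell, 0.670% of cells had a UMI of both unc-4 and Antp, 67.6% had no Hox UMI and 25.7% had an abdominal one, since cells of a class can then lack a UMI of these genes. Thinned to 1000 UMIs, which weighs each cell the same and left out 95 cells, dsx stood at 877 CPM and fru at 714.

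Among lists in TN1-like cells, stress and dissociation genes stood at -0.24 (percentile 1.61) with at least 10 UMIs and at -0.46 (percentile 0.08) against other VAChT clusters; the cause was not tested. Against the median over clusters, monoamine receptors turned from -0.23 to 0.0087, neuropeptides from -1.75 to 0 and the dpr and DIP genes from -0.30 to 0.10. Neuropeptide receptors stood at 0.41 and axon guidance genes at -0.054 in that measure. The median over the 2 TN1-like clusters is their mean, so the measure leans toward TN1-like cells for genes high in either. Between abdominal and Hox-negative cells, neuropeptides stood at 0.23 (percentile 99.8) with at least 500 genes and 0.14 (percentile 98.6) with doublet calls kept, and neuropeptide receptors at -0.20 (percentile 0.74) with at least 500 genes, and the cause was not tested. With VAChT clusters alone, neuropeptides stood at -0.34 (percentile 0.02), apoptosis genes at -0.20 (percentile 5.76), and the dpr and DIP genes turned from -0.28 to 0.0084 (percentile 65.0), which leaves out Gad1, VGlut and Vmat cells by construction.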

Other observations

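The test of stress from dissociation in this part was chosen after the result was seen, and the tests of damaged cells and of a few cells were chosen before. The largest cluster with little dsx, 413 cells of the D. melanogaster library, divided into 5 subclusters. A subcluster of 118 cells had VAChT at 1036 CPM, scro at 782 and toy at 635, with dsx at 14.3 (3.91 to 36.7). A subcluster of 93 cells had AstA at 8360, Gad1 at 2207, VGlut at 1045 and dsx between 2.67 and 37.9. A subcluster of 112 cells, led by CCHa2, AstC and Fer1, had dsx at 94.6, and 50 cells led by Ubx and grn had Antp at 396 and dsx at 50.7. The last, of 40 cells, had dsx at 1134 (987 to 1296) with abd-A at 800, acj6 at 1277, slou at 238 and unc-4 at 217, above the minimum for a dsx cluster. A separate cluster of 16 cells with little dsx had the glutamate transporter gene Eaat1 at 13217, with the glial gene repo at 0 and the neuronal gene nSyb at 2384.

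Levels in TN1-like subclusters differed in how many cells they came from. Dh31 stood at 244 CPM in subcluster 1 and 54.3 in the other TN1-like cells, from 23.7% of the cells of subcluster 1. Nplp1 stood at 430 in subcluster 2 and 59.5 in the others, from 86.7% of its cells. Vmat stood at 246 in subcluster 2, but 2 of its 75 cells held 99.4% of these UMIs, so it is no trait of the subcluster as a whole, and doublet calling did not work in this library.

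The sum of rpr, grim and skl in TN1-like subcluster 5 was 5.95-fold (4.50 to 7.87) that in the other TN1-like cells. Damaged or dying cells are argued against, since the median mitochondrial share was 1.09 times that of the others (1.72% against 1.58%). Stress of dissociation is argued against as the whole cause, since the median log2 ratio of the stress list was 0.16. A few cells are argued against, since the 2 cells with the most held 28.4% of these UMIs. No biological explanation was tested, and the cause stays open.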
